A study of Homo sapiens with 4 samples.

How the data were processed

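U2OS cells were labelled with BrU for 2 h, and 4 libraries were made from the cytoplasmic BrU-labelled RNA, 2 of m6A immunoprecipitate and 2 of input, per the labels. Groups and replicate numbers came from the sample titles. The labels do not say whether the replicates came from separate cultures. The single table used was 1 list of peaks for the whole series, which holds 0 columns of per-sample values. No immunoprecipitate against input test, replicate error or depth per library could therefore be computed.

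Reads were aligned with HISAT2, version not given, to hg38, per the submitters' processing notes. The peak caller, its gene annotation, the way replicates were combined and the strand setting were not given in the sources used here. For each peak the authors deposited a fold enrichment (a linear ratio), a −log10 FDR and a score that is a whole number of unstated meaning. The header does not name the libraries behind the fold, and it was taken as immunoprecipitate over input from the labels. The weakest peak deposited had an FDR of 0.05. Of the deposited widths, 90.9% were multiples of 200 nt, with a median of 600 nt, and 29.7% of peaks were split by a gap. Starts were 0-based: 188 starts plus 1 equalled a RefSeq gene start, against 14 starts as listed. In 2050 minus-strand peaks the block sizes were listed in the order opposite to the block starts, and after reversal all blocks fitted. Coordinates are printed 1-based.

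Peaks were tied to genes by the Ensembl ID and gene name that the authors gave, in place of the planned peak centre. Names were matched to RefSeq symbols and synonyms (GRCh38.p14), which named 11017 peaks (90.8%) and 6987 genes. There were 40 peaks with no name and 12 whose name had been turned into a date by a spreadsheet, and 3 more led to a gene on another chromosome. Regions were taken from the authors' annotation, which names every feature a peak touches. A peak that touches a stop codon was put in a stop codon class first, so the classes depend on peak width.

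Shares have 95% Clopper-Pearson intervals, which cover counting error only. Median folds were compared between regions by two-sided permutation (100000 resamples), adjusted by Benjamini-Hochberg over 6 comparisons. For each gene list, the number of members with a peak was set against 10000 random lists (permuted membership) drawn from 19974 protein-coding genes and matched in 20 bins of genomic length, since transcript lengths were not used here, and the smallest p is 0.0002. That background holds 639 genes with LOC symbols, 0 of which matched a name in the list of peaks, and it was run without them as an alternative added later. Of the 22 lists fixed before the data were examined, the mitochondrially encoded mRNAs and the long non-coding RNAs were not tested. Lists share some genes (BMP2, GADD45A and others), so they are not independent. Strength within lists was compared by the median best fold in 5 length bins. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. On simulated data the list test called 93.5% of lists of 75 genes with a true ratio of 1.6 and 87.5% at 0.5, and 4% at 1. For lists of 30 genes it called 58.5%, 41% and 2%, so short lists that did not pass may still differ. The permutation test of medians called 89% of 500 against 500 peaks with a ratio of 1.2, and 5% at 1. Calls on simulated data used an unadjusted p under 0.05. With the adjustment used for the real data, the shares called would be no higher.

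The genes named were fixed by rule: the 15 genes with the highest fold among the 6068 peaks that are strongest by FDR, with coordinates for the first 5, the 10 genes with most peaks, every m6A writer, eraser and reader, and up to 4 members with the highest fold of each other list. XIST and Y-linked genes were left out, and 2 genes that the rule takes are not reported here. A few other genes are named after their values were seen, and this is said beside them. The alternatives were the 6068 strongest peaks by FDR, FDR in place of fold, other rules for tying peaks to genes, merging peaks under 100 nt apart, other backgrounds and no length matching. Added after the data were seen were a score of at least 10, peaks of 400 nt alone, no overlapping peaks, another denominator, the background without LOC symbols and, for the share of peaks over a stop codon, the strongest peaks. Tests of placement along transcripts, of DRACH and GGACU motifs, of splice junctions and of long exons were planned and not run, since they need a genome and transcript models that were not used here.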

Results

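The data describe N6-methyladenosine (m6A), a methyl mark on adenosine in RNA, in newly made cytoplasmic RNA of U2OS cells, an established human osteosarcoma line. Cells were given bromouridine (BrU), a uridine analogue that is built into new transcripts, for 2 h, and RNA carrying it was pulled out of the cytoplasmic pool and fragmented. Fragments were then immunoprecipitated with an antibody against m6A. The series held 4 libraries, 2 of the m6A immunoprecipitate and 2 of its input. The values analysed were 1 list of m6A peaks for the whole series, with 1 fold enrichment, 1 FDR and 1 score for each peak, so the spread between replicates and the depth of each library were not known from it. The peak values below are the authors' own and serve to describe and rank peaks within this list.

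m6A peaks lay in 7924 genes and numbered 12136. Of the 6987 genes that could be given a RefSeq symbol, 6466 were protein-coding, 285 were long non-coding RNAs, and 117 pseudogenes and 107 transcribed pseudogenes were listed too, whose reads may be shared with their parent genes. In 5127 genes (64.7%) there was 1 peak, in 1873 there were 2 and in 924 there were 3 or more. These counts are of the peaks listed: the peaks of each gene are numbered, and 2051 numbers within genes are absent for a reason not given in the sources used here. The median fold enrichment was 14.2, with quartiles of 9.36 and 23.2, and the range ran from 3.60 to 679. No peak lay on the mitochondrial chromosome, so none of the 13 mitochondrially encoded mRNAs could hold one. Whether the peak caller covered that chromosome is not known here. The highest score of all, 19941, nevertheless belonged to MTATP6P1 (fold 77.7), a nuclear pseudogene copy of the mitochondrial ATP6 gene named here after its value was seen, and its assignment is uncertain because the copies are close in sequence. A score under 10 was listed for 1535 peaks (12.6%). With only the 6068 peaks that were strongest by FDR, 4791 genes held a peak.

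The first question was where in the transcripts the peaks lay. Of the 10050 peaks with an mRNA annotation by the authors, 4402 reached a stop codon (43.8%, 95% interval 42.8 to 44.8, Clopper-Pearson). Counted in the same way, 6894 (68.6%) touched coding sequence, 6635 (66.0%) a 3' UTR and 1853 (18.4%) a 5' UTR, and 1 peak can count under several of these. A peak in the 3' UTR alone was found in 2437 cases and one in the coding sequence alone in 1492, whereas 671 peaks lay in the 5' UTR alone. In protein-coding genes, 7485 of 10319 peaks (72.5%, 95% interval 71.7 to 73.4) were nearer to the end of the gene than to its start. That distance is genomic and includes introns, and the share to be met by chance was not computed. Another 1545 peaks (12.7% of all) were annotated to non-coding RNA and 541 had no annotation. These intervals cover the count of peaks only, and how many peaks would reach a stop codon by chance was not computed, since no transcript models were used here.

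Peaks over a stop codon that did not touch a 5' UTR had a higher enrichment than each of 6 other classes they were compared with. Their median fold was 18.9 over 3865 peaks. It was 14.8 for peaks in the coding sequence alone, 14.8 for peaks spanning the 5' UTR and coding sequence, 12.3 in the 3' UTR alone and 10.1 in the 5' UTR alone. Peaks in non-coding RNA had a median of 9.82 and unannotated peaks one of 9.18. Of the classes not tested, the 537 peaks that touched both a stop codon and a 5' UTR had a median of 20.5, the 403 spanning the coding sequence and 3' UTR one of 14.9, and 48 other mixtures one of 15.1. Each of the 6 differences tested, of 4.07 to 9.67 in fold, had an adjusted p of 1e-05 in a two-sided permutation test, the smallest that 100000 permutations can give. Peaks are not replicates, so p describes this list only. Wider peaks had higher folds, and among peaks of 400 nt the stop codon peaks exceeded those in the 3' UTR alone by 1.54 (12.3 against 10.8), those in the 5' UTR alone by 2.24, those in non-coding RNA by 3.90 and unannotated ones by 2.93, while the differences from peaks in the coding sequence alone (0.276) and from peaks spanning the 5' UTR and coding sequence (0.406) no longer passed the test (adjusted permutation p = 0.501 for both).

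**Figure D1:**
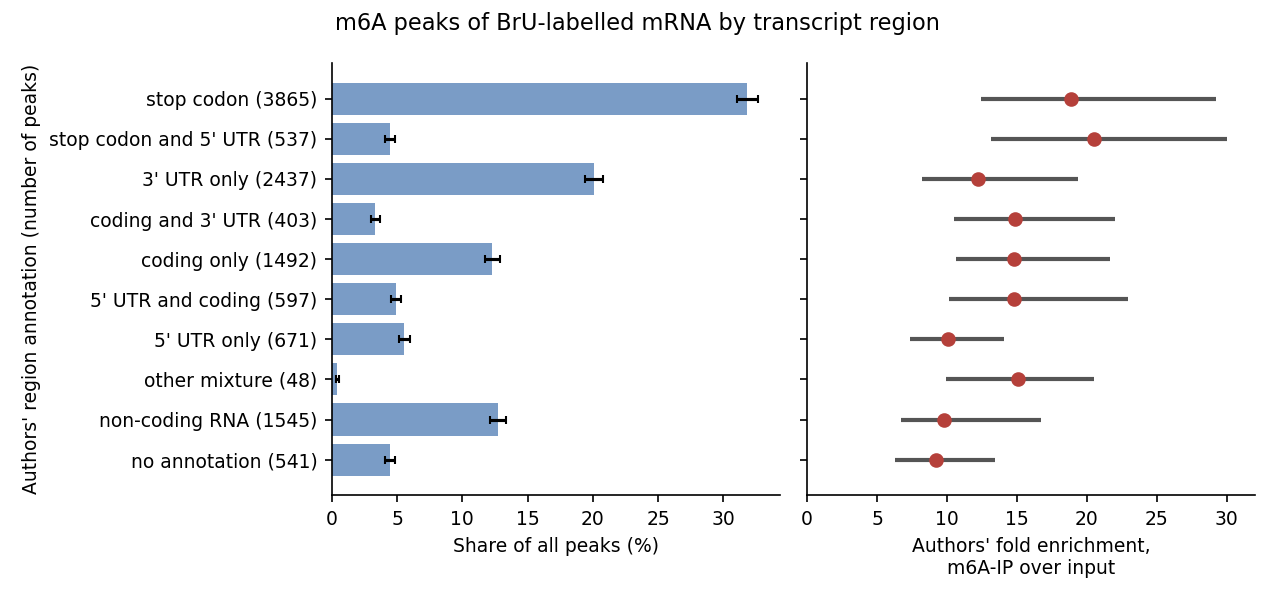
The left panel shows the share of all 12136 peaks (%) in each of the authors' annotation classes, with 95% Clopper-Pearson intervals as error bars, and the right panel the authors' fold enrichment, with the median as a point and the quartiles as a line. Peaks over a stop codon that do not touch a 5' UTR form the largest class, 31.8% of all peaks. Their median fold of 18.9 lies above the 12.3 of peaks in the 3' UTR alone.

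The highest fold belonged to a peak in MTRFR, listed under its older symbol C12orf65, which encodes a mitochondrial protein of the release factor family. This peak covered the stop codon on chromosome 12 from 123254291 to 123257669 (hg38, plus strand) with a fold of 679. Next came P3H4, a gene of the collagen-modifying prolyl 3-hydroxylase family, with a stop codon peak at chromosome 17, 41802087 to 41803393 (minus strand), and a fold of 595. ZKSCAN1, a zinc finger transcription factor, had a 3' UTR peak at chromosome 7, 100037171 to 100038170 (plus strand), with a fold of 436. MTG2, a GTPase tied to the mitochondrial ribosome, had one at chromosome 20, 62201520 to 62203159 (plus strand), with a fold of 411. PIGBOS1, which encodes a small mitochondrial outer membrane protein, had a stop codon peak at chromosome 15, 55317184 to 55317765 (minus strand), with a fold of 390. The next 10 genes included NAIF1 (323), RP5-1198O20.4 (316), the AlkB family dioxygenase ALKBH4 (311), FBXL19-AS1 (294), FAHD1 (288), the GPI anchor mannosyltransferase PIGM (286), the vesicle SNARE VAMP3 (280), NME6 (258) and KANTR (251), with the fold of the strongest peak in brackets. Of these 15 peaks, 5 reached a stop codon, 5 lay in the 3' UTR alone, 4 were annotated to non-coding RNA and 1 spanned the 5' UTR and coding sequence. The order is by fold, which was higher in wider peaks. The MTRFR peak was 1600 nt wide against a median of 600 nt over the list.

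The genes with most listed peaks, a ranking that the absent numbers could alter, encode large proteins in several cases. MUC16, a giant mucin, held 12 peaks, but its best fold was 9.39 and the median score of its peaks was 6. AHNAK2 and RNF213, an E3 ubiquitin ligase, held 11 each, with best folds of 33.5 and 28.7. AHNAK held 10, with a median score of 394.5. TACC2, the cadherin family members FAT1 and FAT4, the transcription factor HIVEP1, the cytoskeletal linker DST and the nuclease gene DNASE1 held 8 each, with best folds from 12.6 in DNASE1 to 53.5 in TACC2. Their median scores were 9.5 in DNASE1 (highest 16), 15.5 in DST, 19.5 in FAT4, 43 in TACC2, 228 in FAT1 and 334 in HIVEP1.

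The share of protein-coding genes with a peak differed with gene length. When genes were put into 10 groups by genomic length, 12.9% of the shortest group held a peak (257 of 1998), against 41.9% of the ninth (836 of 1997) and 36.9% of the longest (738 of 1998). Genes with a peak held 1.2 peaks each in the shortest group and 1.96 in the longest. The lists of genes below were therefore set against random lists matched on length.

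**Figure D2:**
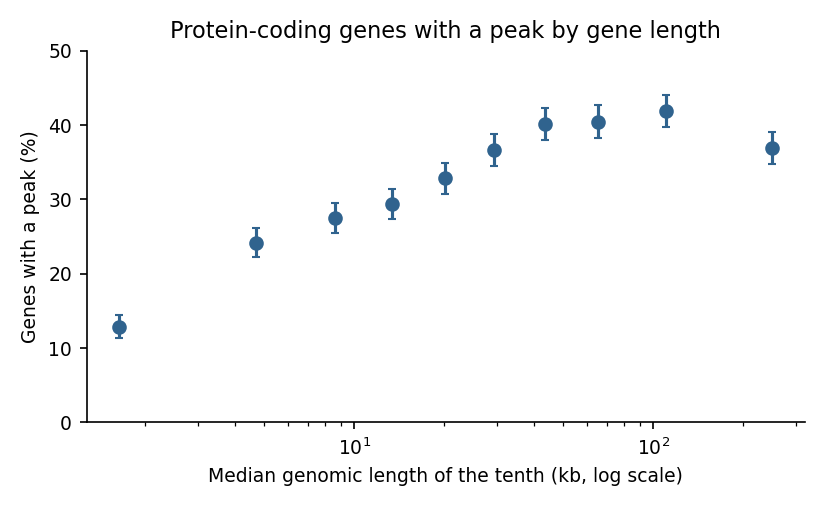
Each point is 1 of 10 groups of the 19974 protein-coding genes by genomic length, placed at its median length (kb, log scale), with the share that held a peak (%) and its 95% Clopper-Pearson interval. The share is 12.9% in the shortest group, highest at 41.9% in the ninth and 36.9% in the longest.

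Which functional groups carried m6A peaks in new RNA was asked with gene lists fixed beforehand. Over all 19974 protein-coding genes 6447 held a peak (32.3%), and 20 lists were compared with 10000 random lists of the same length profile, a two-sided permutation of list membership among genes of like length, Benjamini-Hochberg adjusted over the 20. In 5 lists more genes held a peak than in the matched lists, and in 3 fewer did. Input level is not in the list of peaks, so these comparisons are not matched on expression, and a gene without a peak may not have been expressed. Length here is genomic, and transcript length was not matched.

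Chromatin regulators held peaks in 43 of 50 genes, 2.15 times the matched lists (adjusted permutation p = 0.00133, from an unadjusted 0.0002, the smallest that 10000 lists can give). Their highest folds were those of the histone methyltransferase NSD2 (91.1), the acetyltransferases KAT6B (71.5) and KAT6A (69.1) and the chromatin remodelling subunit ARID1B (49.8). Each of these peaks lay over a stop codon. TGF-beta and BMP signalling genes held peaks in 24 of 29 (2.14 times, adjusted permutation p = 0.00133), with the highest folds in the inhibitory SMAD6 (43.9), the ligand BMP2 (43.2), the corepressor TGIF2 (34.9) and SMAD5 (34.5), a transducer of BMP signals. Wnt and Hippo genes held peaks in 20 of 30 (1.85 times, adjusted permutation p = 0.0064), among them the ubiquitin ligases RNF43 (70.2) and ZNRF3 (63.5), the receptor FZD1 (49.6) and the kinase LATS2 (40.2). For the Wnt and Hippo list the 6068 strongest peaks gave a ratio of 1.71 that did not pass the test (adjusted permutation p = 0.116).

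Immediate-early and short-lived mRNAs held peaks in 28 of 43 genes, 2.74 times the matched lists (adjusted permutation p = 0.00133). Without length matching the ratio was 2.02 (adjusted permutation p = 0.001), below the 2.67 of chromatin regulators and the 2.57 of TGF-beta and BMP signalling genes. MYC, a transcription factor with a short-lived mRNA, had a stop codon peak with a fold of 74.2 and a score of 19038. GADD45B (56.0), a stress-induced gene, FOSB (49.2), a subunit of AP-1, and IER3 (46.0) followed, and the IER3 peak overlapped a peak of another gene. Targets of p53, which is wild type in U2OS cells, held peaks in 17 of 28 genes (1.82 times, adjusted permutation p = 0.0114). The highest folds were those of PHLDA3 (126) and TIGAR (125), then the phosphatase PPM1D (30.5) and the p53 ubiquitin ligase MDM2 (28.6), and the PHLDA3 and MDM2 peaks overlapped those of other genes. The p53 call was lost with the 6068 strongest peaks (1.89 times, adjusted permutation p = 0.102) and without overlapping peaks (1.68 times, 0.064), where the ratio stayed near its value over all peaks. It was also lost against genes with a peak or above the median length (1.36 times, adjusted permutation p = 0.132), and against that background the immediate-early list had a ratio of 1.03 (adjusted permutation p = 1). Short genes enter that background only with a peak, which pulls lists of short genes towards a ratio of 1 by construction.

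Cytosolic ribosomal proteins held peaks in 7 of 77 genes, 0.384 times the matched lists (adjusted permutation p = 0.0064). The highest folds were in RPL37 (52.4), RPS7 (24.7, a peak with no region annotation), RPL28 (21.5) and RPS24 (17.3). These genes have many near-identical pseudogene copies, so peaks assigned to them, and their absence, are uncertain. The call was lost with the 6068 strongest peaks (0.452 times, adjusted permutation p = 0.114). Against genes with a peak or above the median length the ratio was 0.9495 (adjusted permutation p = 1). That background pulls lists of short genes towards 1 by construction, so this value does not bear on the call. Neuronal markers held no peak in 16 genes (adjusted permutation p = 0.0114) and lymphoid and erythroid markers none in 18 (adjusted permutation p = 0.0125). Hepatocyte markers held 1 in 16 genes (adjusted permutation p = 0.103), in CPS1 (fold 8.51, a peak with no region annotation). With the 6068 strongest peaks the neuronal and lymphoid lists still had a ratio of 0, with adjusted permutation p values of 0.102 and 0.121. Against genes with a peak or above the median length both ratios were 0 too. There the neuronal list passed the test (adjusted permutation p = 0.0147) and the lymphoid list did not (0.396). Of the 15 osteoblast lineage markers 4 held a peak, among them DLX3 (47.5), BMP2 (43.2) and RUNX2 (19.2), which did not differ from matched lists (adjusted permutation p = 0.989).

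The m6A machinery itself was represented. Of 12 writer genes 8 held a peak, 1.96 times the matched lists (adjusted permutation p = 0.0764). They were RBM15 (fold 42.7, 3 peaks), the methyltransferase METTL16 (36.2), ZC3H13 (30.2, 4 peaks), the methyltransferase subunit METTL14 (25.8), RBM15B (23.9), VIRMA (20.3), the cap methyltransferase PCIF1 (18.9) and WTAP (14.8). The catalytic subunit METTL3 had no peak, nor had CBLL1, ZCCHC4 and METTL5. With the 6068 strongest peaks the writer list passed the test (2.78 times, adjusted permutation p = 0.0416). Among 18 erasers and readers 11 held a peak (1.61 times, adjusted permutation p = 0.129), and without length matching the list passed the test (1.88 times, adjusted permutation p = 0.0458). The readers IGF2BP3 (67.7) and IGF2BP1 (58.7) led, followed by YTHDF2 (32.7), YTHDF3 (20.8), YTHDC1 (18.4), the demethylase FTO (17.1), ELAVL1 (16.04), YTHDF1 (15.1), PRRC2A (14.6), the demethylase ALKBH5 (14.4) and IGF2BP2 (4.70, score 5). The best peaks of IGF2BP3 and YTHDC1 had no region annotation by the authors. No peak was listed for YTHDC2, HNRNPA2B1, HNRNPC, FMR1, FXR1, FXR2 or LRPPRC.

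The remaining lists did not differ from matched lists in the share of genes with a peak. DNA damage response and repair genes held peaks in 24 of 44 (1.44 times, adjusted permutation p = 0.0729), led by FANCM (38.2), the nuclease ERCC4 (32.4), the helicase BLM (31.9) and FANCA (31.2), whose peak overlapped another gene's; the list passed the test with the 6068 strongest peaks (adjusted permutation p = 0.0416) and without length matching (0.00844). Cell cycle regulators held peaks in 14 of 40 (adjusted permutation p = 0.989), led by the replication licensing factor CDT1 (88.5), RBL1 (59.4), E2F3 (32.9) and the proliferation marker MKI67 (21.4). Respiratory chain subunits encoded in the nucleus held peaks in 22 of 74 (1.05 times, adjusted permutation p = 0.989), with ATP5F1D (87.6), NDUFA2 (63.1, a peak with no region annotation), NDUFB9 (37.3) and NDUFA11 (24.7) highest. The median best fold of those 22 genes was 9.78, below the 18.2 of random lists of genes with a peak (adjusted permutation p = 0.0064), the only one of the 16 lists with at least 5 such genes to pass this second test, which was chosen after the list of peaks had been seen. That second test was matched on genomic length alone. Peak width, number of peaks, score and input level were not matched, so the reason for the lower fold was not tested.

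Replication-dependent histones held peaks in 6 of 53 genes (adjusted permutation p = 0.857), and since their copies are close in sequence H2BC15 (49.8), H3C6 (12.3), H2BC5 (11.96) and H3C8 (11.51) are uncertain. Against random lists not matched on length the histone list had fewer genes with a peak (0.350 times, adjusted permutation p = 0.002). Heat shock proteins and chaperones held peaks in 8 of 21 (adjusted permutation p = 0.857), with HSPA1B (23.1), HSP90AA1 (18.2), DNAJB1 (16.6) and HSPA8 (15.7) highest, and HSPA1B is uncertain because HSPA1A is nearly identical. Glycolytic enzymes held peaks in 6 of 19 (adjusted permutation p = 1), led by HK2 (30.6), PFKFB3 (24.2), PFKP (12.8) and PGK1 (10.2). Translation factors held peaks in 11 of 31 (adjusted permutation p = 0.989), led by EIF3I (26.3), EIF3A (21.2), EIF3F (20.5) and EEF1D (19.7). Cytoskeleton and extracellular matrix genes held peaks in 12 of 30 (adjusted permutation p = 0.857), led by the integrin ITGA5 (42.4), COL5A1 (30.5), THBS1 (25.9) and TUBB (25.3), the last of which overlapped another gene's peak. Of 20 abundant long non-coding RNAs, which were not tested, 9 held a peak, with OIP5-AS1 (50.7), CYTOR (34.5), TUG1 (23.2) and MIR22HG (21.5) highest.

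**Figure D3:**
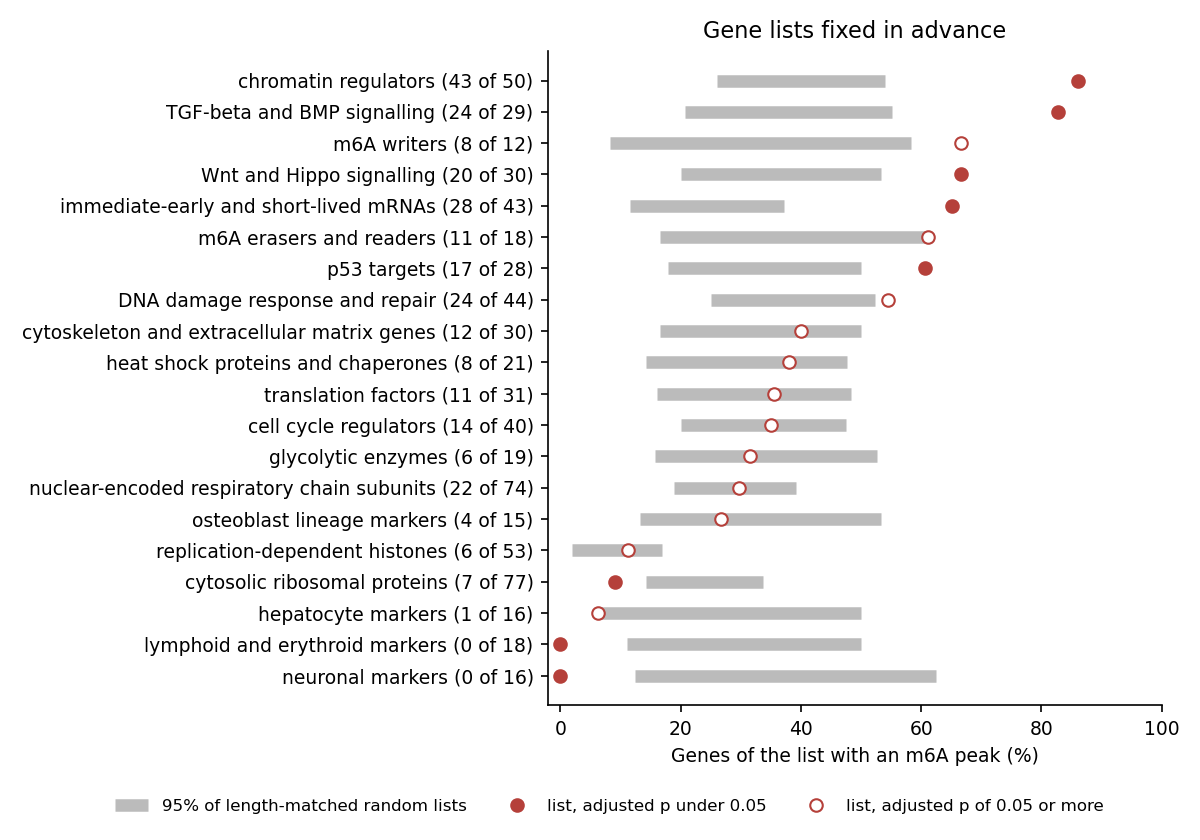
Each row is a gene list, the point gives the share of its genes with an m6A peak (%), filled where the adjusted p is under 0.05, and the grey bar spans 95% of 10000 random lists matched on gene length. Chromatin regulators (43 of 50) and TGF-beta and BMP signalling genes (24 of 29) lie above the grey bars, and ribosomal proteins (7 of 77) below theirs.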

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

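No paired analysis was possible because the list holds 1 value per peak and none per library, and for the same reason no replicate could be left out and DESeq2 was not run. Settings chosen beforehand that need transcripts or sequence (other representative transcripts, peak end points, windows, motifs, exon lengths and exon overlap) were not run, and overlap with the RefSeq gene span stood in for the last. Chosen after the data were seen were the score of at least 10, peaks of 400 nt, peaks that overlap no other gene's, all peaks as denominator, the background without LOC symbols and, for the share of peaks over a stop codon, the strongest peaks by FDR. The strongest peaks by FDR numbered 6068 by construction, in 4791 genes, 53.3% of those on mRNA reached a stop codon, and 0 lists lay below matched lists, where fewer genes with a peak leave less room for a low count. With a score of at least 10 the share over a stop codon was 46.3%, 66.1% of genes held 1 peak, and 33.9% of the longest of 10 length groups held a peak; with all peaks as denominator the share over a stop codon was 36.3%. Among 400-nt peaks the stop codon difference was 0.276 from the coding sequence alone and 0.406 from the 5' UTR and coding sequence. Against genes with a peak or above the median length, 3 lists lay above and 1 below; short genes enter that background only with a peak, which pulls lists of short genes towards a ratio of 1 by construction. Without LOC symbols 15.5% of the shortest group held a peak, and all 20 list ratios kept their direction and side of the threshold. Ratios that crossed or reached 1, none past the threshold before, were for the 6068 strongest peaks the respiratory chain (0.465), cell cycle (0.727), heat shock (0.505), translation (0.480), cytoskeleton (0.908) and osteoblast (1.32) lists; without length matching the respiratory chain (0.922) and histones (0.350); against genes with a peak or above the median length the respiratory chain (0.887), histones (1), glycolysis (1.55) and cytoskeleton (0.984); and with a score of at least 10 the respiratory chain (0.923) and cytoskeleton (0.941). Apart from the constructions named, the cause was not tested. Depth per library is unknown, so how far weak peaks limit the calls cannot be said. Merging peaks under 100 nt apart changed no count. Since 90.9% of widths were multiples of 200 nt, listed peaks of a gene may never lie that close, so this setting may be no check.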

Other observations

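The gene families, the chromosomes and the tests of shared reads and of counting without regard to strand were chosen after the data were seen, as were the genes named here outside the fixed rule. Genes were grouped by the letters before the first digit of their symbol, and 96 families of at least 20 genes were set against length-matched random lists. In 6 families more genes held a peak. These were the transcription factor families ZBTB (35 of 42, 2.48 times, adjusted permutation p = 0.0048), ZSCAN (14 of 21, 2.02 times, 0.0162) and ZNF (333 of 517, 1.89 times, 0.0048), the RNA polymerase subunits POLR (20 of 33, 1.95 times, 0.0115), the RNA-binding RBM genes (22 of 39, 1.6 times, 0.0459) and the WD repeat WDR genes (31 of 58, 1.51 times, 0.0339). In 12 families fewer did, among them the olfactory receptors (0 of 392, adjusted permutation p = 0.0048), the keratin-associated proteins (0 of 94, 0.0115), the beta-defensins (0 of 39, 0.0048), the keratins (3 of 55, 0.0064) and the cytochrome P450 genes (8 of 56, 0.0144). Expression was not matched.

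By chromosome, 6 of 23 lay above length-matched lists and 4 below. On the X chromosome 165 of 848 protein-coding genes held a peak (0.639 times, adjusted permutation p = 0.00115), and on chromosome 4 it was 212 of 770 (0.804 times, 0.00115). Chromosome 16 had the highest ratio, with 347 of 854 genes (1.31 times, adjusted permutation p = 0.00115), followed by chromosome 22 (178 of 451, 1.22 times, 0.00552) and chromosome 17 (431 of 1169, 1.21 times, 0.00115). Expression, copy number and transcript length were not matched. Related genes can lie together on 1 chromosome, so genes are not independent draws and these p values may be too small. Whether m6A itself differs by chromosome cannot be told from these counts.

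Stop codon peaks that did not touch a 5' UTR had a median fold 6.60 above peaks in the 3' UTR alone. A peak's fold rose with its width, from a median of 8.32 at 200 nt to 22.0 at 1000 nt, and among 400-nt peaks the difference was 1.54 (845 and 768 peaks, permutation p = 1e-05, the smallest possible), which argues against width as the whole cause while much of the difference went with it. Input level stays open: in peaks of 1 bin of 200 nt the fold followed the score and 1 further whole number, which may be an input read count (all 725 peaks not used to set the constants came out whole within 0.01, for numbers up to 11, but only 24 of 957 above that), and within equal numbers the difference was 0 (71 and 248 peaks, permutation p = 1). That value met what had been written in advance for input level as the cause, but these peaks differed by only 0.489 before any matching, so the test was judged void after its result was seen. No biological explanation was tested.

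ZNF genes, most of them zinc finger transcription factors, held peaks in 333 of 517 cases. Their median best fold was 24.4, which was 6.42 above that of other protein-coding genes (permutation p = 1e-05, the smallest possible). However, 51.1% of ZNF peaks reached a stop codon against 41.0% of other protein-coding peaks. The best fold is the highest over the peaks of a gene, and it was not matched on region, width or number of peaks. Genomic length does not account for the count of ZNF genes with a peak, which was 1.89 times that of lists matched on it (permutation p = 0.0002, the smallest possible). Transcript length was not matched and stays open. If paralogs each took the reads they share, the related genes clustered on chromosome 19 would be expected to hold peaks more often. Instead 57.6% of the 250 ZNF genes there held one, against 70.8% of the 267 elsewhere (Fisher's exact p = 0.00182). How reads that fit several genes were treated is not known here. Dropping them could lower the share in the clusters, and expression was not matched, so shared reads stay open. Expression in U2OS cells remains open, and no biological explanation was tested.

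Peaks of genes on opposite strands overlapped in 137 pairs. Counting without regard to strand would give both genes the same reads where they overlap. Equal scores were found in 0 of the 137 pairs, against 32 of 316 pairs on the same strand (Fisher's exact p = 9.48e-06). Genes on opposite strands may not share the same bins, which was not checked, so this comparison cannot rule out such counting. In 28 pairs the stronger score was at least 1000, and in 19 of them, such as DDIT4 (score 15050) over RP11-442H21.2 (37), the weaker score was under 1% of the stronger. Leakage of a small share of reads to the wrong strand may account for such weak antisense peaks, and it cannot be told apart from true antisense RNA here, since Spearman's rho between the 2 scores was 0.279 over the 28 pairs (permutation p = 0.154, bootstrap 95% upper limit 0.60). Weak antisense peaks beside strong ones are therefore uncertain.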
